A study of Microcebus murinus with 8 samples.

How the data were processed

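Small RNA from blood plasma was sequenced in 8 samples from grey mouse lemurs (Microcebus murinus, a small primate), 4 from animals on a diet whose fat came from dairy and 4 from animals on a diet whose fat came from vegetable sources. Groups were taken from the sample titles. Samples are numbered as in the titles, 1 to 4 for dairy fat and 5 to 8 for vegetable fat, and these numbers pair no animals across the diets. The column headers of the 4 vegetable fat tables carry other running numbers than the titles, with the same diet. Nothing in the labels says that each sample came from a different animal, so p-values measure the spread between these samples. No untreated or baseline sample was analysed here, so each difference is of one diet against the other.

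Per the labels' protocols, plasma RNA was extracted with the miRNeasy Micro kit and libraries were made with the QIAseq miRNA kit. Per the submitters' processing notes, cutadapt 3.4 was used. The aligner, the counting tool, the reference set, the treatment of molecular identifiers and any filter on microRNAs are not given in the sources used here. The deposited tables list the same 108 microRNAs in every sample, and the deposited values are reads per 1000000 (RPM) relative to these 108 alone, since each sample's values summed to 1000000. RPM values are shares of a fixed total, so a rise of one abundant microRNA lowers the others. Names carry the mouse lemur prefix, without the arm (5p or 3p) of the hairpin. No genome was used here, so no positions are given.

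In each sample all 108 values lay within 0.01 of a whole multiple of one step, the value of 1 read. The step gave an implied total of 1408536, 3103305, 3437717 and 3210200 reads in dairy samples 1 to 4 and of 3286351, 1855670, 4004131 and 1061434 reads in vegetable samples 5 to 8. These totals sum the 108 listed microRNAs only, and deeper and shallower refer here to these totals, not to all reads sequenced. A floor of 3 reads corresponds to 0.749 RPM in the deepest and 2.83 RPM in the shallowest library. Whether reads or unique molecules were counted is not known, so such floors cover counting error only. Too few low values were listed to rest a count model on these implied reads, and the planned count tests were replaced by limma, as the design foresaw for normalized values. The 3 pairs miR-103a and miR-103b, miR-92a and miR-92b, and miR-218a and miR-218b held identical values in every sample, so the members of each pair cannot be told apart here. Both members of each pair count in the implied totals. No pair of files held the same values or differed by counting noise alone (smallest chi-square 322.1 per degree of freedom on implied reads), so each was used as 1 sample. This does not show that no libraries are repeats from one animal.

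The main test was limma 3.58.1 (R 4.3.3) with trended, robust variance on log2(RPM + 1), for microRNAs at 1 RPM or more in at least 4 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left out miR-152, miR-212, miR-34b and miR-615, and 104 microRNAs were tested. Fold changes are vegetable fat over dairy fat on the log2(RPM + 1) scale, which understates the change of scarce microRNAs, with limma's 95% confidence intervals. Single quantities were compared by two-sided exact permutation tests over the 70 assignments of 8 samples, whose smallest p is 0.0286. Fixed lists of microRNAs with at least 3 tested members were tested with camera (correlation of 0.01, and estimated) and with fry. Of 18 lists, 14 had enough members, and those for liver, muscle and heart, and endocrine pancreas (0 members listed) and for gut and epithelium (1 listed) did not. List names were matched without the arm, and a name without a letter was used only where one list member could match it, so miR-10 stood for miR-10b and miR-365 for miR-365a. List membership came from general knowledge of human and rodent tissues.

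The lists, the tests, the alternatives and the rule for named microRNAs were fixed before the data were examined, apart from the changes given here. The plan had set the filter and the variance between diets for counts. For RPM they were replaced by 1 RPM in at least 4 samples and by log2(RPM + 1) without further scaling. Named are the microRNAs past the threshold, filled up to 20 with those of smallest p, the 10 most abundant, and 15 fixed names of which 6 were listed. The planned haemolysis index, miR-451a over miR-23a, is not analysed here, and miR-486 over miR-23b was used in its place, chosen after the listed names were seen. Other choices made after seeing the data were the count of list members against the median of all microRNAs, the count of microRNAs above 0 in place of 10 reads, median-of-ratios scaling for the variance between diets, a trimmed mean of log ratios as scaling, sample weights, the read total or that index as a covariate, identical pairs counted once, limma without its trend and robust options, the 6 most abundant microRNAs left out, and the shallowest and the deepest library left out. Those libraries were vegetable samples 8 and 7, so that fit set only vegetable samples 5 and 6 against the 4 dairy fat samples. Also run were other pseudocounts (0.5 and 5), filters, median-of-ratios and upper quartile scaling, the erythrocyte list left out, and each sample left out in turn, where the filter asked for 1 RPM in 3 samples.

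The procedure was tested on simulated data for the vegetable against dairy comparison, with the 104 tested microRNAs at their real means and residual spreads and independent errors. Each of the 100 simulations held 20 changed microRNAs together, 5 at each fold size. The larger changes ease the Benjamini-Hochberg cutoff for the smaller ones, so the recovery rates may be too high where few microRNAs change. It recovered 8.4% of changes of 1.5-fold, 37.4% of 2-fold, 77.8% of 4-fold and 90.2% of 8-fold, and 5.57% of all calls were false. In simulated data a list of 8 microRNAs shifted 2-fold passed camera at p under 0.05 in 100% of simulations, and an unshifted list in 5%. Independent errors make the list test look stronger than it is where members vary together. All 8 members were shifted in the same direction, and that p was not adjusted. The real test adjusted over 14 lists, most of them with fewer tested members, so 100% is not its power.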

Results

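Plasma microRNAs were profiled in grey mouse lemurs fed a diet based on dairy fat (4 samples) or on vegetable fat (4 samples), to ask whether the source of dietary fat was reflected in circulating microRNAs. The tables gave RPM for 108 microRNAs per sample. Implied read totals ran from 1408536 to 3437717 in the dairy fat samples and from 1061434 to 4004131 in the vegetable fat samples. All 108 microRNAs were above 0 in 6 samples and 107 in dairy samples 2 and 3.

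Among the 108 microRNAs analysed, let-7 microRNAs, miR-191 and miR-486 took most of the reads on both diets. MiR-451a and miR-16, which are abundant in red blood cells, miR-223 of myeloid cells and platelets, and miR-122 of liver are not analysed here, so shares and ranks hold only among the 108. The 6 most abundant microRNAs, let-7b, miR-191, let-7a, let-7g, let-7f and miR-486, took 77.8% ± 2.26 (SD, n = 8) of the reads. Let-7b stood at 180700 ± 14470 RPM on dairy fat and 182400 ± 24900 on vegetable fat (SD, n = 4 each). MiR-191 stood at 184300 ± 21280 RPM on dairy fat and 178400 ± 24900 on vegetable fat. MiR-486, which is abundant in red blood cells, stood at 75460 ± 15000 RPM on dairy fat and 90200 ± 23810 on vegetable fat. The next most abundant were miR-30e, miR-26b, miR-26a and miR-103a, at mean levels over all samples between 27320 and 13050 RPM. The value of miR-103a was shared in full with miR-103b.

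**Figure D1:**
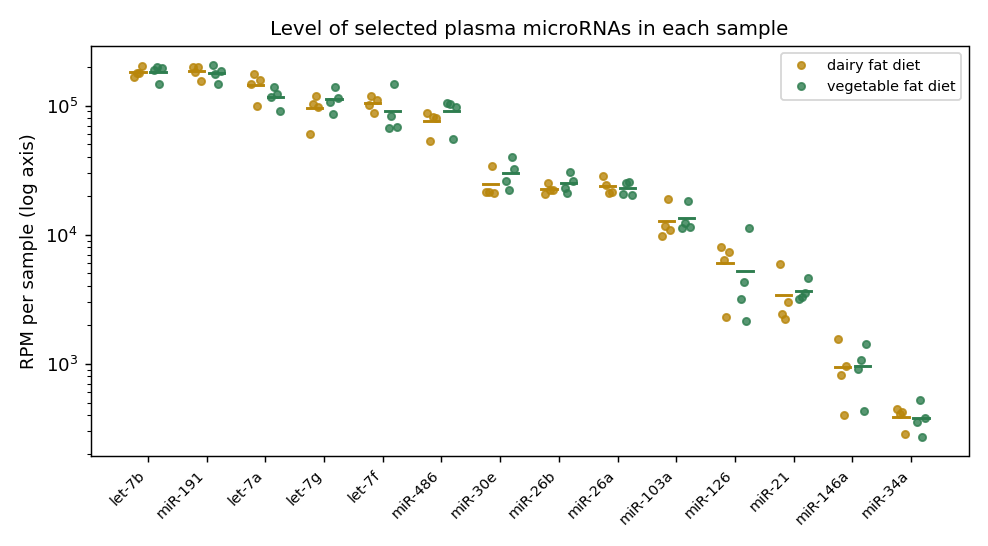
RPM on a log axis for the 10 most abundant microRNAs and 4 others of the fixed names, 1 point per sample, with dairy fat samples in ochre, vegetable fat samples in green, and a bar at each diet's mean. The diets overlap for every microRNA shown; let-7b has means of 180700 RPM on dairy fat and 182400 RPM on vegetable fat.

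The comparison of vegetable fat with dairy fat called no microRNA. By limma 0 of 104 had an adjusted p under 0.05, and 0 had an unadjusted p under 0.05. Chance gives 5.2 of the latter on average, but microRNAs that vary together make that count uneven. Over the 35 splits of the 8 samples into 4 and 4 the median was 1 such microRNA, and 25 splits had any. The smallest p was 0.116, for miR-19b, and the smallest adjusted p was 0.999. No microRNA of the 108 separated the 4 vegetable fat samples from the 4 dairy fat samples, where chance alone would give on average 2.86% of them, or 3.1. The estimates lay between −0.61 and 1.23 on the log2 scale with a median of 0.07, 64 above 0 and 40 below. The scaling decided that balance: with upper quartile factors the median moved to −0.20, with 21 estimates above 0 and 83 below.

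How large a change could have gone unseen differed between microRNAs. The 95% confidence interval had a median width of ± 0.84 on the log2 scale, and for 44 of the 104 it lay within a 2-fold change in either direction. The narrowest intervals were those of let-7b, miR-191, miR-26b, miR-26a and let-7a, all among the 10 most abundant. For let-7b the estimate was 0.01 with an interval from −0.32 to 0.33, and for miR-191 it was −0.05 with an interval from −0.39 to 0.29. For miR-26b and miR-26a it was 0.15 (−0.24 to 0.55) and −0.04 (−0.44 to 0.36). For miR-103a, of the pair miR-103 and miR-107 that acts on insulin signalling, it was 0.08 (−0.48 to 0.65). Intervals were wide for miR-126, an endothelial microRNA (−0.34, −1.55 to 0.86), and miR-146a, a feedback regulator of NF-kappaB signalling (0.06, −1.0 to 1.13). The miR-126 estimate ran from −0.81 without vegetable sample 8 to −0.0077 without vegetable sample 7. For miR-21 and miR-34a, which targets SIRT1, the estimates were 0.21 (−0.51 to 0.93) and −0.05 (−0.72 to 0.62).

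Among the 20 microRNAs with the smallest p, 14 had estimates above 0 and 6 below, and none passed the test. Only let-7g among them changed sign under another scaling. Leaving out 1 sample moved 18 of the 20 by over 1.5 times, miR-101 and miR-3959 being the exceptions. MiR-19b, of the miR-17 to miR-92 cluster, stood at 525.3 ± 179.7 RPM on dairy fat and 844.2 ± 357.1 on vegetable fat (SD, n = 4 each; fold 1.58, log2 estimate 0.66 ± 0.38 SE, limma adjusted p = 0.999), and all 4 vegetable fat samples lay above the dairy fat median. Its estimate was 0.42 without vegetable sample 7, 0.43 without dairy sample 1 and 0.16 without the shallowest and the deepest library. Those libraries were vegetable samples 8 and 7, so that fit left only vegetable samples 5 and 6 for vegetable fat. The miR-19b relatives miR-17 and miR-18 had folds of 1.23 and 1.24. MiR-101 stood at 46.87 ± 12.66 RPM and 71.53 ± 12.63 (fold 1.54), with 3 of the 4 vegetable fat samples above every dairy fat sample. MiR-374a stood at 80.69 ± 31.80 and 131.4 ± 64.47 RPM (fold 1.58), with an estimate of 0.66 that was 0.37 without vegetable sample 7 and 0.25 without the shallowest and the deepest library. The fold estimates of miR-140, a microRNA of cartilage, miR-148b, miR-872, miR-484, miR-186, miR-182 and miR-30e lay between 1.22 and 1.43. The largest estimate, 1.23 for miR-542, rested on few reads, since it stood at 1.49 ± 1.12 RPM on dairy fat and 6.61 ± 6.29 on vegetable fat, and 2 of the 4 vegetable fat samples lay below the dairy fat median. With a pseudocount of 5 the miR-542 estimate was 0.68, and with read total as a covariate 0.93. MiR-542 also fell with read total (slope −1.35 for each doubling of reads, limma adjusted p = 0.00508). Its 2 highest values, 10.78 and 13.19 RPM, came from vegetable samples 6 and 8, the vegetable fat libraries with fewest reads.

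The signs of the let-7 family moved with the scaling, as did those of all microRNAs: of its 6 members 3 were above 0 and 3 below on RPM, 1 above and 5 below with the trimmed mean, and 0 above and 6 below with upper quartile factors. Against the median of all microRNAs 1 of the 6 lay above under each scaling, so these flips follow the common shift. Let-7a stood at 145000 ± 32980 RPM on dairy fat and 116900 ± 19880 on vegetable fat (log2 estimate −0.29 ± 0.21 SE, −0.56 with upper quartile factors; limma adjusted p = 0.999), and all 4 vegetable fat samples lay below the dairy fat median. Let-7f stood at 104200 ± 13110 and 91120 ± 37850 RPM (−0.27 ± 0.25). Let-7g stood at 94900 ± 24850 and 111600 ± 22430 RPM (0.26 ± 0.23, or −0.01 with upper quartile factors). The others of the 20 smallest p with estimates below 0 were miR-342, which is found in lymphocytes and monocytes (fold 0.655), miR-28 (0.688), miR-296 (0.798) and miR-3959 (0.67). Single samples decided much of the miR-342 estimate of −0.61, which was −0.21 without vegetable sample 7, −0.29 without dairy sample 1 and −0.92 without vegetable sample 5. That of miR-28, −0.54, was −0.11 without vegetable sample 7, −0.25 without dairy sample 1 and −0.88 without dairy sample 3. MiR-28 also fell with read total (slope −0.91 for each doubling of reads, limma adjusted p = 0.00958), and with read total as a covariate its estimate was −0.74. MiR-3959 lay near the floor of 3 reads, at 2.21 ± 0.68 RPM on dairy fat and 1.17 ± 0.57 on vegetable fat, and its estimate of −0.58 was −0.22 with a pseudocount of 5.

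**Figure D2:**
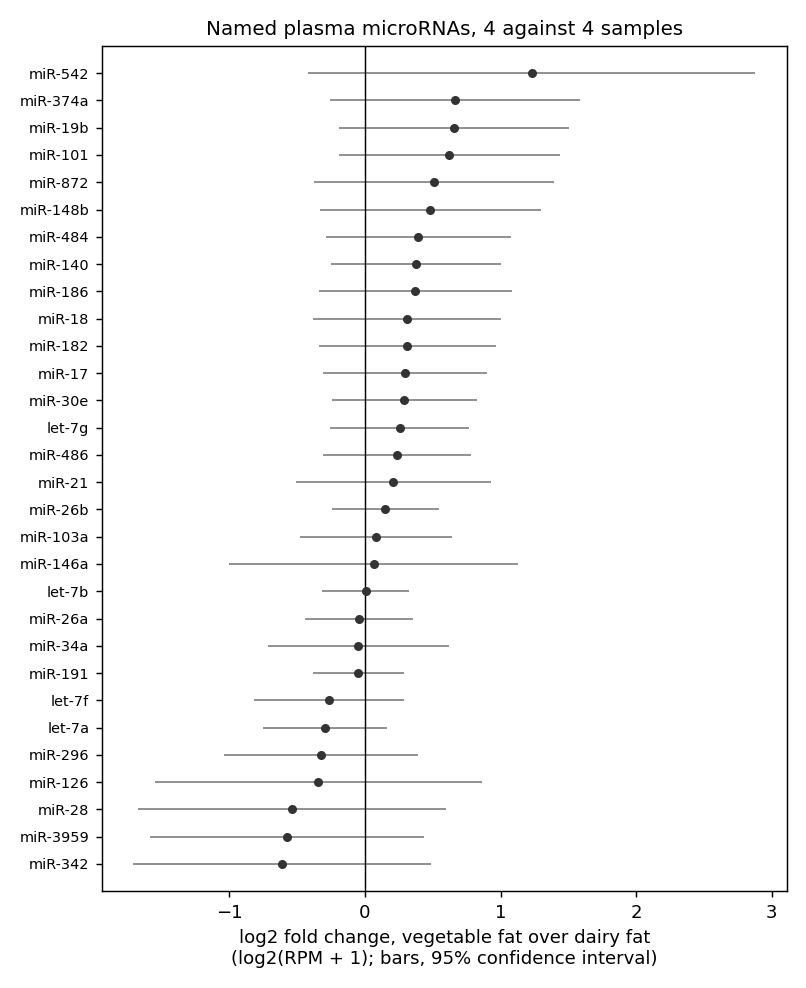
Log2 fold change (vegetable fat over dairy fat, log2(RPM + 1) scale) of the 30 named microRNAs, sorted by estimate; points are limma estimates and bars 95% confidence intervals from 4 samples per diet. Every interval includes 0, and miR-542 has the largest estimate, 1.23.

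Lists of microRNAs by cell of origin or function were compared as groups, and none of the 14 passed at an adjusted p of 0.05 with camera, with camera with estimated correlation, or with fry, in its test of one direction or of either. Adjusted over the list alone, 0 members passed by limma in each list, as over all microRNAs tested. Since the scaling moved all estimates together, members are counted against the median of all microRNAs. Those counts were equal under the 4 scalings, which follows from the common shift and is no separate support for them. The smallest list p was for the miR-17 to miR-92 clusters, where all 3 tested members, out of 13 fixed, (miR-17, miR-19b and miR-92a) lay above that median, with a list median of 0.30 (camera p = 0.0156, adjusted p = 0.218; adjusted p = 0.623 with an estimated correlation). MiR-18 and miR-20, named without a letter, could not be matched to this list. All 4 tested members of the erythrocyte list, out of 12 fixed, (miR-486, miR-92a, miR-15a and miR-182) lay above it too, with estimates between 0.14 and 0.31, 3 of which were below 0 with upper quartile factors (camera adjusted p = 0.321). The reads this list took were 8.65% ± 1.73 on dairy fat and 10.2% ± 2.36 on vegetable fat (SD, n = 4 each; exact permutation p = 0.371).

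MicroRNAs linked to metabolism lay on both sides of the median. In the lipid and cholesterol list 3 of 5 lay above it (list median 0.11, camera adjusted p = 0.929). In the glucose and insulin list, which holds the miR-29 family, 5 of 11 did (0.03, adjusted p = 0.837). The estimates for miR-29a, miR-29b and miR-29c were −0.06, −0.12 and 0.14. In the adipose list 3 of 7 lay above (0.05, adjusted p = 0.929). For the last 2 lists the median and mean were above 0 while camera, which compares with the other microRNAs, gave the direction as down. The list of milk-abundant microRNAs had only 9 of its 15 fixed members tested, and 5 of these 9 lay above the median (list median 0.15, camera adjusted p = 0.837). The 9 took 6.48% ± 0.78 of the reads on dairy fat and 6.73% ± 0.47 on vegetable fat (exact permutation p = 0.600). The miR-30 family had 2 of 3 members above (camera adjusted p = 0.604) and took 3.57% ± 0.73 and 4.13% ± 0.73 of the reads (exact permutation p = 0.257, the smallest of the 14 lists; adjusted p = 0.943).

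The lists for brain and for blood and vessel cells also failed the test. The brain list held miR-128, miR-132 and miR-138, which are enriched in neurons, with estimates of 0.11, −0.21 and 0.09 (camera adjusted p = 0.929, direction down, mean −0.002). Platelet microRNAs had 3 of 7 members above the median of all (adjusted p = 0.604), with a list median of 0.03, a mean of −0.04 and a camera direction of down. Leukocyte microRNAs had 1 of 5 above (adjusted p = 0.321), endothelial ones 1 of 5 (0.604) and inflammation-related ones 2 of 7 (0.604). The let-7 family with miR-98 had 1 of 6 above, let-7g (list median −0.06, camera adjusted p = 0.321), and took 53.8% ± 5.28 of the reads on dairy fat and 51.6% ± 3.59 on vegetable fat (exact permutation p = 0.514). The imprinted DLK1-DIO3 cluster, represented by 3 of 33 fixed members (miR-136, miR-381 and miR-409), had estimates of −0.45, 0.00 and 0.01 (camera adjusted p = 0.604, direction down, mean −0.15). MiR-411a and miR-411b, which did not match the list's miR-411 by name, had estimates of −0.24 and −0.095.

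Diet accounted for 4.72% of the variance of the whole profile (exact permutation p = 0.886), where random splits of 8 samples average 14.3%. With 1 sample left out it ran from 3.9% without dairy sample 4 to 10.8% without vegetable sample 7 (exact permutation p from 0.6 to 0.971), and was over 1.5 times the value of all 8 also without dairy samples 1 or 3 (7.6% and 10%) or vegetable samples 6 or 8 (7.5% and 8.3%). Random splits average a larger share than 14.3% once a sample is left out, so these rises do not come from the sample removed alone. The median Pearson correlation of samples across microRNAs, which are not independent replicates, was 0.980 within dairy fat, 0.980 within vegetable fat and 0.985 between the diets. The first principal component held 71.3% of the variance, and its scores averaged −0.29 ± 5.65 on dairy fat and 0.29 ± 7.45 on vegetable fat (SD, n = 4 each; exact permutation p = 0.886). Vegetable sample 7 and dairy sample 3 lay at one end, and dairy sample 1 and vegetable sample 8 at the other.

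**Figure D3:**
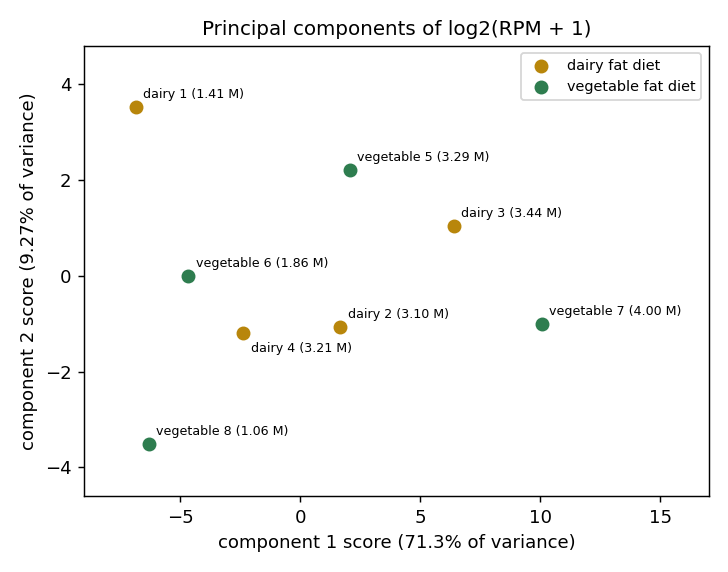
Scores of the 8 samples on the first and second principal component of log2(RPM + 1), with the share of variance on each axis and the implied reads beside each point (M, 1000000 reads). The diets are intermixed along the first component, which holds 71.3% of the variance, and the libraries with fewest reads lie on its left.

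Measures of library quality overlapped between the diets. Implied reads averaged 2.79 ± 0.93 M (1000000 reads) on dairy fat and 2.55 ± 1.34 M on vegetable fat (SD, n = 4 each; exact permutation p = 0.857). MicroRNAs with 10 or more implied reads numbered 100 ± 0.82 and 99.5 ± 1.29 (exact permutation p = 0.771). Only 108 microRNAs were listed, and 107 or 108 were above 0 in each sample, so this count says little about library quality. The log2 ratio of miR-486 to miR-23b, used in place of the planned haemolysis index, was 4.68 ± 0.79 on dairy fat and 4.78 ± 0.50 on vegetable fat (exact permutation p = 0.857). The ratio is no clean measure of red cells, since miR-23b itself was lower in deeper libraries (slope −0.99 for each doubling of reads, limma adjusted p = 0.00147), and miR-486 had a slope of −0.27 (limma adjusted p = 0.246). The sign of its difference between the diets depended on single libraries: the difference, 0.10, ran from −0.22 without dairy sample 1 to 0.41 without dairy sample 3.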

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

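Of 92 groups of 4 samples examined for a value far from the rest, 6 stood out, and chance gives about 1 in 20, or 4.6. In the dairy fat group, miR-342 was 4930 RPM in sample 1 against 1750 to 2210 in the others, miR-30e was 34300 RPM in sample 3 against 21200 to 21400, and miR-18 was 1200 RPM in sample 3 against 711 to 765. Dairy sample 1 also had an implied 1.41 M reads (M, 1000000) against 3.1 to 3.44 M. In the vegetable fat group, miR-486 was 54800 RPM in sample 7 against 97500 to 105000, and miR-103a was 18100 RPM in sample 7 against 11300 to 12300.

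The 5 microRNA values come from dairy samples 1 and 3 and vegetable sample 7, 3 of the 4 samples at the ends of the first principal component. That component is computed from the same RPM values, so this overlap is no separate evidence of a pattern. The relation of the component to read totals is weighed among the other observations.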

How the results depend on the processing

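The alternatives by trimmed mean, sample weights, covariates, identical pairs, limma options, detection above 0, median-of-ratios scaling of the variance between diets, and without the 6 most abundant microRNAs or the shallowest and deepest library were chosen after seeing the data. The count of microRNAs past the threshold was 0 by limma in the 23 alternatives run, with smallest adjusted p from 0.578 (without vegetable sample 7) to 1, and 0 to 4 had an unadjusted p under 0.05. The numbers of lists past the threshold, by camera or by share of reads, were likewise 0 in each of the alternatives run for them. The edgeR, DESeq2 and voom alternatives and those using miR-451a, miR-16 or miR-23a were not run. No paired analysis was possible because the sample numbers differ between the diets.

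Of 680 refitted log2 estimates of the named microRNAs 640 kept their sign, and the 40 others were not called. Upper quartile factors shifted the median of all microRNAs from 0.07 to −0.20 and gave −0.0077 for let-7g, −0.26 for let-7b, −0.028 for miR-486, −0.11 for miR-26b, −0.18 for miR-103a, −0.20 for miR-146a and −0.054 for miR-21. The trimmed mean gave −0.072 for let-7b and −0.014 for miR-146a. Sample weights gave 0.026 for miR-342, 0.10 for miR-191 and 0.20 for miR-34a. Read total as a covariate gave −0.010 for let-7b and −0.13 for miR-146a. Without the 6 most abundant, miR-103a was −0.0080 and miR-146a −0.028. Without the shallowest and the deepest library, miR-342 was 0.16, miR-30e −0.0029, miR-17 −0.038, miR-18 −0.031, miR-191 0.055, miR-26b −0.030, miR-103a −0.061 and miR-34a 0.16. Both libraries left out there were vegetable fat, samples 8 and 7, so only vegetable samples 5 and 6 stood for that diet. Leaving out 1 sample moved 28 of the 30 named estimates by over 1.5 times, and 14 of the 30 were nearest 0, or past it, without vegetable sample 7. In these refits let-7b ran from −0.042 to 0.11, miR-26a from −0.10 to 0.047, miR-103a from −0.072 to 0.29, miR-34a from −0.22 to 0.10, miR-146a from −0.29 to 0.41 and miR-191 from −0.13 to 0.038. The miR-486 to miR-23b difference ran from −0.22 to 0.41 and the read total difference from −0.72 to 0.26 M (1000000 reads). The difference in detected microRNAs was −0.5 at 10 reads and 0.5 above 0. For these reversals the cause was not tested, apart from the upper quartile shift of all estimates. With 4 samples per diet and 20 microRNAs changed together, 37.4% of simulated 2-fold changes were recovered. Most changes of that size in single microRNAs would thus be missed.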

Other observations

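The tests on read totals and cell lists below were chosen after the result was seen, except the thinning test, the removal of the 6 most abundant microRNAs and the count of list calls over splits. Across samples of both diets, more microRNAs were called against the implied read total than against diet. With diet kept in the model, 36 of the 104 microRNAs varied with the implied read total at an adjusted p under 0.05 by limma. Of these, 34 were lower and 2 (miR-15a and miR-590) higher in libraries with a larger total over the listed microRNAs. The 34 include both members of the identical pair miR-218a and miR-218b. The count of 36 fell to 15 without dairy sample 1 and to 21 without vegetable sample 7. The slopes for each doubling of reads were −1.75 on the log2 scale for miR-145, a microRNA of smooth muscle, −1.86 for miR-214, −1.44 for miR-100 and −1.02 for the endothelial miR-126. Members of the imprinted DLK1-DIO3 cluster had slopes of −2.13 (miR-381), −1.82 (miR-409) and −1.53 (miR-136), though as a list they did not pass (camera adjusted p = 0.179; adjusted p = 0.823 with an estimated correlation). In the opposite direction, miR-15a had a slope of 0.83.

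Scores on the first component rose with the log2 read total over the 8 samples (Pearson r = 0.85, exact permutation p = 0.0082; Spearman rho = 0.95, exact permutation p = 0.0011; 1 relation computed, so the adjusted values are the same). Without vegetable sample 8 and dairy sample 1, the samples farthest from the median, r was 0.81 (exact permutation p = 0.024). Sampling noise of the reads in the shallow libraries is argued against, since thinning all libraries to the smallest total left 68.6% ± 1.3 (SD of 20 thinnings) of the variance on this component, against 71.3%. So is a squeeze by a few microRNAs, since 71.5% remained without the 6 most abundant, and so is diet as its main source, with an exact permutation p of 0.886 and a difference of 0.57 against a standard deviation of 6.61 within diets. A candidate explanation is a varying content of microRNAs from platelets and vessel wall. All 7 platelet and all 5 endothelial members (miR-126 and miR-221 are in both) had negative slopes, as had 76 of all 104 microRNAs. By limma 4 of the 7 platelet and 5 of the 5 endothelial members passed, but miR-191 of the platelet list had a slope of only −0.08. Neither list passed camera (adjusted p = 0.22 for platelet and 0.0889 for endothelium), and with an estimated correlation the larger adjusted p was 0.823. The median slope was −0.69 for the platelet list, −1.05 for the endothelial list and −1.82 for the DLK1-DIO3 cluster. The platelet and vessel wall explanation thus stays open. So do fewer starting molecules in the shallow libraries, which thinning of reads does not mimic, and a lower RNA yield that changes both the read total and the profile, neither of which was tested.

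Other splits of the 8 samples into 4 and 4 cannot test the counts past the threshold against chance. With a real count of 0 by limma all 35 splits reach it, for microRNAs and for the fixed lists alike. The highest other split called 28 microRNAs, and the highest for lists gave 2. The split with 28 put dairy samples 1 and 4 with vegetable samples 6 and 8, the 4 lowest on the first component, so it points to the same structure of the samples as that component and adds no separate evidence for it. The split by read total, with dairy samples 1 and 2 and vegetable samples 6 and 8 as the shallower 4, called 0 by limma, with 25 at an unadjusted p under 0.05.

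The let-7f estimate, −0.27 on the log2 scale, moved with single samples of the vegetable fat group and with the scaling. It was −0.52 without vegetable sample 7, −0.14 without vegetable sample 5, −0.15 without vegetable sample 8, −0.53 with upper quartile factors and −0.51 with sample weights. Without vegetable sample 7 the unadjusted limma p was 0.0054, the smallest over the 23 alternatives, and the adjusted p 0.578, where the other alternatives gave 0.903 to 1.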
